A study of Homo sapiens with 6 samples.

How the data were processed

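RNA-seq libraries from H358 lung cancer cells were made with a stranded mRNA kit and read in pairs, per the labels. The knockdown group carried lentiviral short hairpin RNAs against ESRP1 and ESRP2 and the other group a control knockdown, with 3 libraries each. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the size of the library) for each Ensembl gene and library. TopHat 1.4.1, Cuffdiff 2.2.0 and the hg19 build are named in the submitters' processing notes, and the annotation release and the strand setting of the counting are not given in the sources used here. Of 54607 rows, 27772 were listed at 0 in all libraries. An exact 0 can be a failed estimate, since U2AF1, a splicing factor that every cell uses, was listed at 0 in every library. Of the tested rows 84 held a 0 in some library, 2 of the genes named hold one, and a further named gene holds a value that is 0 in effect. Coordinates are those deposited for hg19; starts, which the gene lengths showed to be counted from 0, were raised by 1 so that positions count from 1. A GENCODE v29 annotation was used only for gene types, transcript lengths and GC content, matched by Ensembl ID for 45529 rows, and a symbol table for current names.

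FPKM values carry no totals. Relative depth was read from ratios of low values (below 0.3 FPKM) between libraries. Of these ratios, 59.9% to 64.8% lay on ratios of small whole numbers within 0.03 on the log2 scale. Values spread evenly from -2 to 2 would do so in 26.9%. The whole-number ratios were placed around the most common ratio, so values near it count by construction and the comparison is not a test. The depths read this way are estimates of relative depth only. Total depth is unknown, and no interval was derived from it.

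Differential expression was computed with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided) on log2(FPKM + 1), for the 13611 rows with a mean of at least 1 FPKM over the 6 libraries, as knockdown minus control, without a replicate block. The Benjamini-Hochberg adjusted p threshold was 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low genes. The label replicate numbers did not pair the libraries. Gene lists were tested with limma's camera, with a preset correlation of 0.01 and adjustment over the 29 lists, on log2 values. None of the 18 lists called passed with an estimated correlation. A higher correlation does not account for every such loss, so a loss does not by itself show that a list's members are correlated. For cholesterol synthesis the unadjusted camera p went from 6.5e-09 with the preset correlation to 0.0030 with the estimated one. The estimate was below the preset 0.01 for cholesterol synthesis (-0.033), mesenchymal structural genes (-0.016) and tight junctions (-0.013), among other called lists. With fry, which asks whether a list's genes move one way on balance, 20 lists were called. The steps were tested on simulated libraries for this comparison (13611 genes, 50 changed at each size): 70% of genes changed 1.25-fold were recovered, 82% at 1.5-fold, 92% at 2-fold and 98% at 3-fold, with 3.39% of calls false, and 5 of 5 moved lists and 0 of 20 unmoved lists were called. The changed genes were a far smaller share of all genes than the 16.7% called in the real data. The noise was normal, with the variances that limma estimated, so the model held by construction. The recovery and the share of false calls therefore describe that setting only. The simulated genes also varied independently of each other. Real lists had estimated correlations of up to 0.54 (ribosomal proteins), so the simulation cannot show how often an unmoved list is called here.

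Groups, tests, lists and the rule for named genes were chosen before the data were examined. The named genes were ESRP1 and ESRP2, 16 landmark genes of the epithelial to mesenchymal transition and of splicing, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap (rows of small RNA families apart, as recognised by symbol prefixes that did not cover a U1 row), up to 4 called members of each list by smallest adjusted p, and members that went against their list. Clustered protocadherins and other families by symbol root, and BMP4, ID1, ID4, ENOSF1, ATOH8, HES1 and JAG1, were chosen after the data were seen. The lists covered junctions, tight junctions, keratins, epithelial and mesenchymal genes, EMT factors, splicing regulators, genes with ESRP-regulated splicing, interferon, antigen presentation, NF-kB, S phase, mitosis, TGF-beta, ERK, YAP and TAZ, growth factor receptors, integrins, stress responses, cholesterol, hypoxia, lung lineage, NRF2, RNA interference, ribosomal proteins, reference genes, electron transport and histones. Alternatives were a replicate block, a pseudocount of 0.1, no filter, a stricter filter of 5 FPKM, median-ratio and TPM scaling, no intensity trend, leaving out each library, and for lists the estimated correlation and fry. A correction for GC content and transcript length (values for 96.6% of tested genes) the removal of 44 tested rows on haplotype and unplaced contigs, and a constant of 0.013 on the log2 scale added to the knockdown libraries, which moves the median of all genes as the GC and length correction does, were added after the data were seen. Some genes and a list, which was among the 18 called, are not reported here. Figures were drawn with matplotlib 3.10.9.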

Results

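RNA was measured in H358 cells, a human non-small cell lung cancer line with an epithelial character, after lentiviral short hairpin RNAs had been directed at the epithelial splicing regulators ESRP1 and ESRP2 together, and in cells with a control knockdown. Each group held 3 libraries (n = 3 in every mean ± SD that follows), described as biological triplicates. The values were FPKM per Ensembl gene, which carry no read totals. Steps of 1 read among the low values put the depth of knockdown replicates 1, 2 and 3 at 0.992, 1.42 and 1.24 times that of control replicate 1, and the depth of control replicates 2 and 3 at 1.66 and 1.65 times. These are estimates, and the total depth is unknown. The first principal component of the tested genes, with 34.4% of the variance, separated the 3 knockdown libraries from the 3 control libraries.

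The comparison asks which genes differ in RNA level between cells with hairpins against both ESRP genes and cells with a control knockdown. ESRP protein was not measured in these data. Each group carries its own constructs. For every difference described below, effects of the constructs other than through ESRP therefore cannot be told apart from effects of lower ESRP. The targeted genes were examined first. ESRP1 (ENSG00000104413, hg19 chromosome 8, 95653302 to 95719694) stood at 11.9 ± 0.30 FPKM in the knockdown and 72.9 ± 0.56 FPKM in the control, which is 16.3% of the control level. The log2 fold change of log2(FPKM + 1) was -2.52 (SE 0.03, limma adjusted p = 2.3e-08). ESRP2 (ENSG00000103067, chromosome 16, 68259871 to 68270487) stood at 8.40 ± 0.32 FPKM in the knockdown and 15.5 ± 0.36 FPKM in the control, 54.2% of the control level, with a log2 fold change of -0.81 (SE 0.04, limma adjusted p = 1.1e-04). For both genes the 3 knockdown libraries lay below the 3 control libraries.

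**Figure D1:**
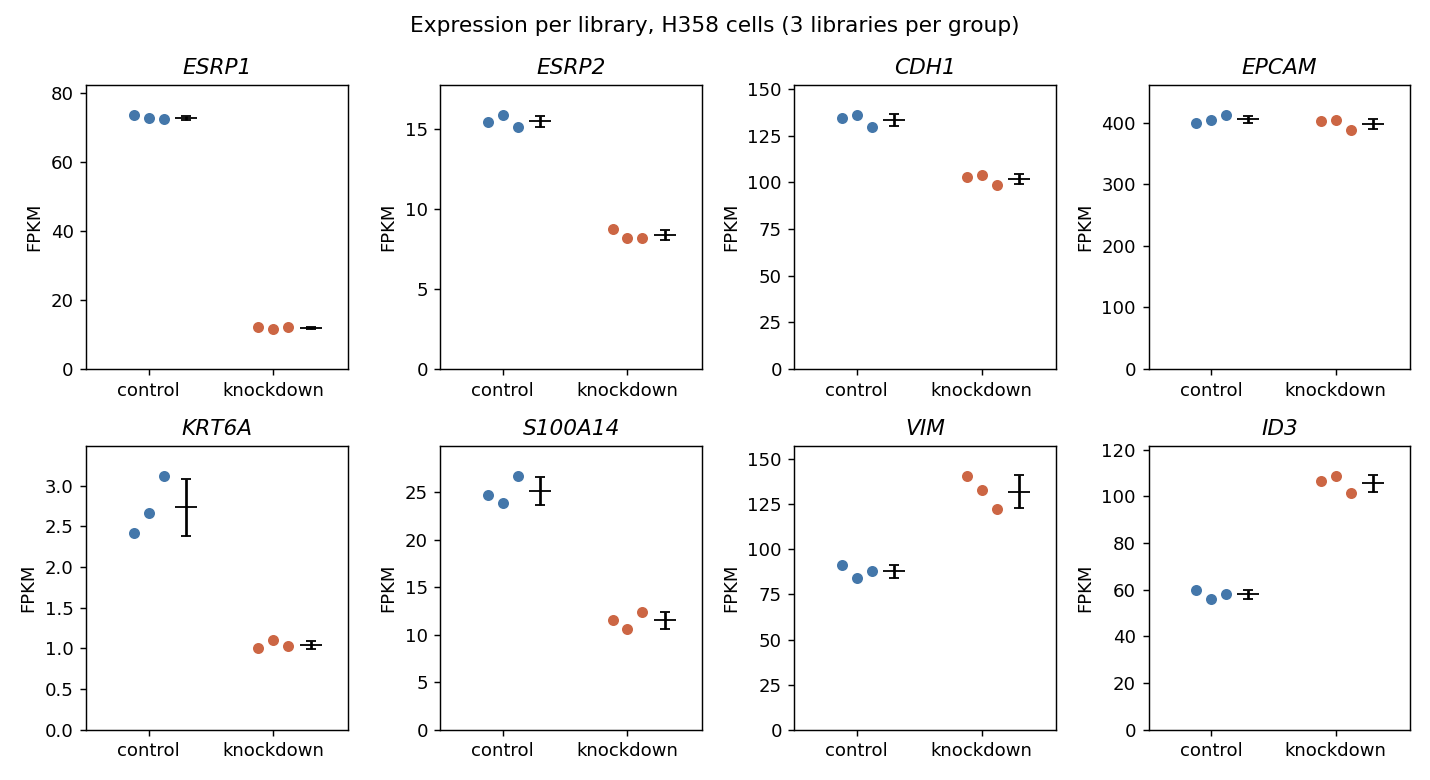
FPKM of 8 genes (vertical axes, from 0) in each of the 3 control and 3 knockdown libraries (points), with the mean and SD of each group (black bars). ESRP1 fell to 16.3% and ESRP2 to 54.2% of control, CDH1, KRT6A and S100A14 were lower and VIM and ID3 higher in the knockdown, and EPCAM was not called (adjusted p = 0.54).

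Across the transcriptome the changes were many and small. Of 13611 genes tested with limma, 2278 changed, 890 upward and 1388 downward, and 4472 had an unadjusted p below 0.05. The median size of a called change was 0.23 on the log2 scale. Only 84 called genes changed at least 1.5-fold and 9 at least 2-fold, 5 of them upward and 4 downward. The groups did not overlap for 38.1% of tested genes, where chance gives 10%. Of the calls, 60.9% were lower in the knockdown. That share was 57.5% after median-ratio scaling and 67.0% after TPM scaling. It was 51.1% after each library's trend on GC content and transcript length was removed, with 2517 genes then called, and 53.1% after a constant of 0.013 on the log2 scale was added to the knockdown libraries, both chosen after the data were seen. The count was smaller when any 1 library was left out, and it depended on which one. It was 1448 without knockdown replicate 1, 1362 without knockdown replicate 2, 1415, 1213 and 1187 without control replicate 1, 2 or 3, and 1983 without knockdown replicate 3.

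**Figure D2:**
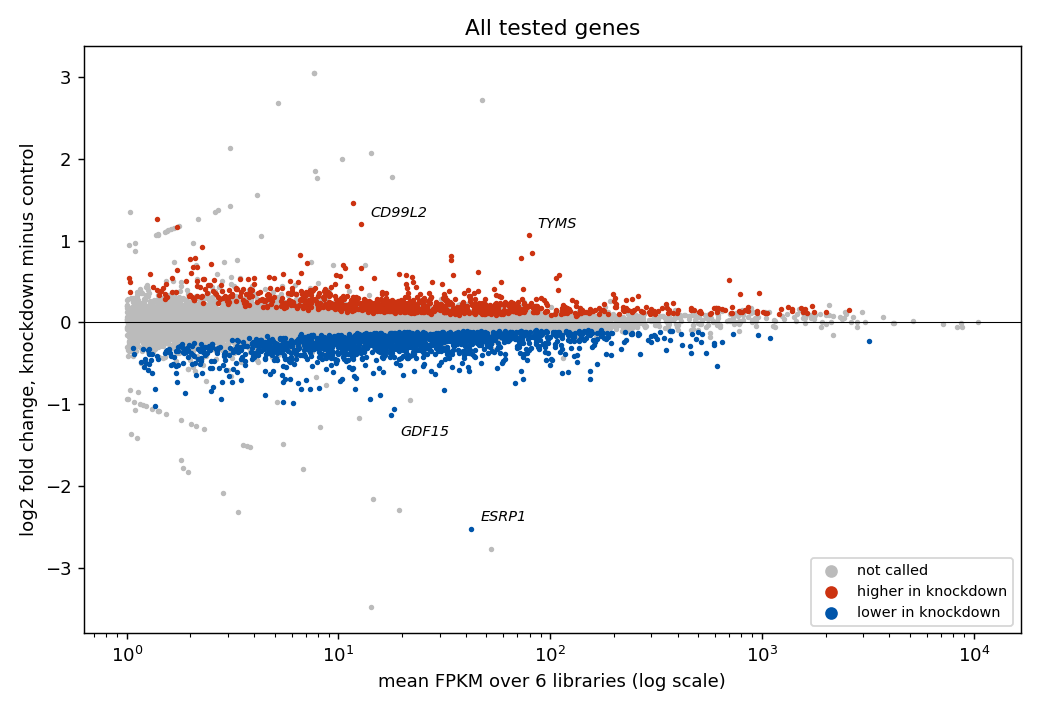
Log2 fold change of log2(FPKM + 1), knockdown minus control (vertical axis), against mean FPKM over the 6 libraries (horizontal axis, log scale) for the 13611 tested genes, coloured by whether limma called them higher (890), lower (1388) or neither. ESRP1 has the lowest value among called genes at -2.52, and of the 56 genes that lie at least 1 log2 unit from 0 without being called, 53 hold a 0 in at least 1 library.

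Genes of epithelial junctions, keratins and transcription factors were examined in 4 lists, each ranked lower by camera with a preset correlation and none called with an estimated correlation. Of 18 tested genes of adherens junctions and desmosomes, 12 fell and 2 rose, counts that were the same when adjusted over the list alone. JUP, which encodes plakoglobin, went from 90.0 ± 0.31 to 65.3 ± 1.1 FPKM. CDH1, which encodes E-cadherin, went from 133 ± 3.3 to 102 ± 2.8 FPKM (log2 fold change -0.39, limma adjusted p = 5.0e-04), and CDH3, P-cadherin, from 174 ± 1.2 to 141 ± 1.4 FPKM. The desmosomal cadherins DSC2 and DSG2 were the exceptions, with log2 fold changes of 0.23 and 0.13, of which the DSG2 call was lost without knockdown replicate 1 or control replicate 3 (adjusted p up to 0.061). The epithelial adhesion molecule EPCAM stood at 398 ± 8.3 and 405 ± 6.1 FPKM (adjusted p = 0.54). The list ranked lower than other genes by camera (adjusted p = 8.2e-06; adjusted p = 0.076 with an estimated correlation). Of 28 tight junction and polarity genes, 7 fell and none rose, the same counts as when adjusted over the list alone. They included LSR, a tricellular junction protein, from 92.1 ± 1.7 to 56.7 ± 1.1 FPKM, CLDN4 and CLDN1, which encode claudins, with log2 fold changes of -0.41 and -0.53, and the polarity gene LLGL2 (-0.38). By camera the adjusted p was 8.8e-04, and the adjusted p was 0.092 with an estimated correlation.

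Epithelial keratins and surface proteins fell in 18 of 26 tested genes and rose in none, and in 21 when adjusted over the list alone. KRT7 went from 642 ± 8.0 to 540 ± 4.5 FPKM and KRT18 from 649 ± 10 to 537 ± 12 FPKM, while KRT6A, a keratin of stratified epithelia present at a low level, went from 2.73 ± 0.35 to 1.04 ± 0.051 FPKM. ELMO3 had a log2 fold change of -0.33. The camera adjusted p was 9.7e-10 (adjusted p = 0.076 with an estimated correlation). Among 17 epithelial transcription factors, 8 fell and none rose, or 10 when adjusted over the list alone. GRHL1, a grainyhead factor, went from 9.58 ± 0.59 to 5.04 ± 0.43 FPKM and TFAP2C from 7.09 ± 0.097 to 3.90 ± 0.33 FPKM, and KLF4 and EHF had log2 fold changes of -0.36 and -0.42. The list had a camera adjusted p of 6.9e-05 and an adjusted p of 0.084 with an estimated correlation.

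Of 21 mesenchymal structural genes, 8 rose, 2 fell and 11 were not called, or 9 and 3 when adjusted over the list alone. Camera gave the list an adjusted p of 0.0020 (adjusted p = 0.11 with an estimated correlation). VIM, the intermediate filament vimentin, went from 87.9 ± 3.6 to 132 ± 9.2 FPKM (log2 fold change 0.58, limma adjusted p = 8.7e-04). CDH11, a mesenchymal cadherin, went from 63.8 ± 0.70 to 85.3 ± 2.0 FPKM, the matrix proteoglycan gene LUM from 22.8 ± 1.3 to 32.4 ± 0.93 FPKM, and LOXL2, a matrix crosslinking enzyme, from 40.0 ± 0.45 to 47.0 ± 1.3 FPKM. CDH2, which encodes N-cadherin, had a log2 fold change of 0.45 (adjusted p = 0.039), a call lost in 4 of 6 fits that left out a library (knockdown replicate 1 or 2, or control replicate 1 or 2, with adjusted p up to 0.099). S100A4 and the matrix gene FN1 were lower, with log2 fold changes of -0.21 and -0.11. The S100A4 call was lost without knockdown replicate 1 or control replicate 1 or 3 (adjusted p up to 0.065), and the FN1 call (adjusted p = 0.048) was lost in every such fit except the one without knockdown replicate 3 (adjusted p up to 0.14).

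The transcription factors of the epithelial to mesenchymal transition were not called as a list (camera adjusted p = 0.66; adjusted p = 0.70 with an estimated correlation). Of 9 tested, SNAI1 and SNAI2 rose with log2 fold changes of 0.26 and 0.17, and FOXC1 and SOX9 fell with -0.23 and -0.15, the same 2 and 2 when adjusted over the list alone. Each of these 4 calls was lost when some single libraries were left out, SNAI1 without knockdown replicate 2 or control replicate 2, FOXC1 also without control replicate 3, and SNAI2 and SOX9 in every fit except the one without knockdown replicate 3 (adjusted p up to 0.084 over the 4 genes). ZEB1 at 0.863 ± 0.12 and 0.787 ± 0.092 FPKM in knockdown and control, and ZEB2 at 0.531 ± 0.15 and 0.550 ± 0.15 FPKM, were below the level needed for testing.

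**Figure D3:**
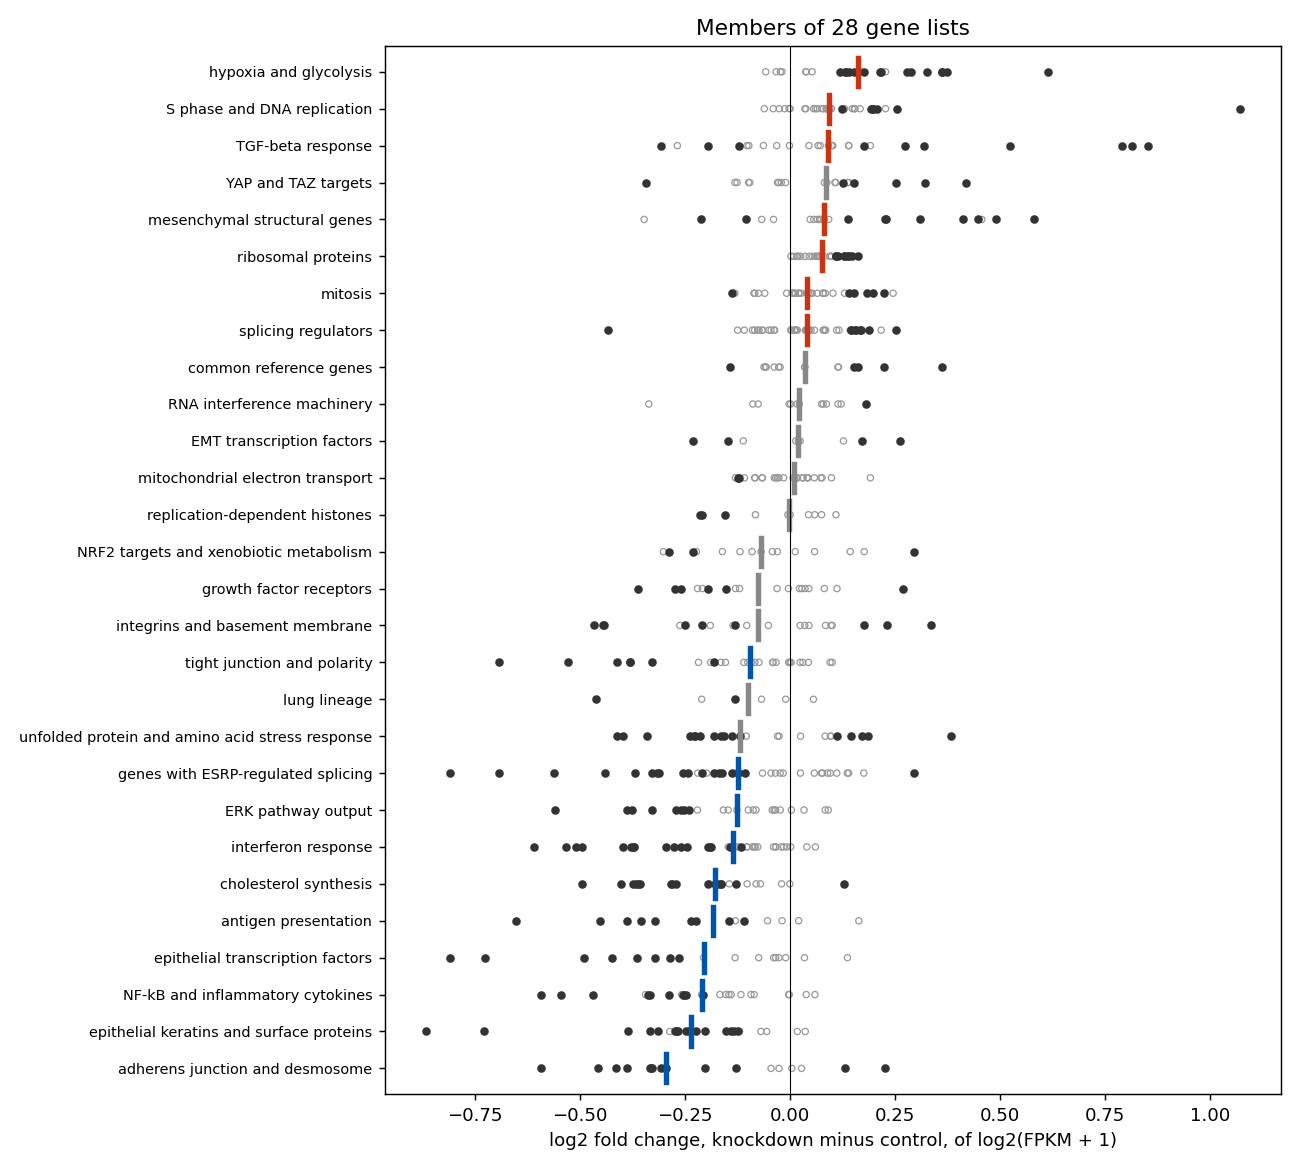
Log2 fold change of log2(FPKM + 1), knockdown minus control (horizontal axis), of the tested members of 28 gene lists (rows, ordered by median). Filled points are genes called by limma, open points are not, and the thick bar is the list median, red or blue where camera called the list higher or lower and grey where it did not. Medians run from -0.30 for adherens junctions and desmosomes to 0.16 for hypoxia and glycolysis.

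Among 25 tested genes that respond to TGF-beta, 7 rose and 3 fell, or 9 and 4 when adjusted over the list alone. ID3 and ID2, inhibitors of basic helix-loop-helix factors, went from 58.1 ± 1.9 to 106 ± 3.8 FPKM and from 24.4 ± 0.96 to 43.7 ± 1.9 FPKM. THBS1, which encodes thrombospondin 1, went from 52.9 ± 2.8 to 92.2 ± 3.9 FPKM, and the matrix gene TGFBI from 576 ± 25 to 828 ± 20 FPKM. IL11, TGM2 and BHLHE40 were lower (log2 fold changes of -0.31, -0.19 and -0.12), but these calls were lost in 5, 4 and 4 of 6 fits that left out a library, with adjusted p up to 0.084. For the list as a whole, camera gave an adjusted p of 0.0068, and the adjusted p was 0.31 with an estimated correlation. The list was not split by the direction in which its genes respond. Its rank therefore does not show whether TGF-beta signalling was higher or lower.

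Gene levels do not show splicing itself, but the genes whose splicing ESRP proteins are known to regulate could be examined for their level. Of 37, 17 fell and 1, RALGPS2, rose (log2 fold change 0.29, a call lost without control replicate 2 at an adjusted p of 0.053), or 18 and 3 when adjusted over the list alone. LSR and GRHL1, named above, had the lowest adjusted p, followed by ARFGAP2, from 26.9 ± 1.2 to 19.5 ± 0.70 FPKM, and BAIAP2, from 25.8 ± 0.62 to 21.4 ± 0.45 FPKM. The list had a camera adjusted p of 0.0014 and an adjusted p of 0.13 with an estimated correlation. It shares 7 members with other lists, and among the 30 it does not share, 12 fell and 1 rose. These 30 did not pass by camera (adjusted p = 0.052 over the unshared parts of the lists), with a median log2 fold change of -0.09 against -0.12 for all 37. The textbook ESRP targets FGFR2 (2.32 ± 0.17 and 2.63 ± 0.25 FPKM in knockdown and control), CTNND1 (117 ± 2.1 and 120 ± 0.42 FPKM), ENAH (35.8 ± 1.1 and 33.1 ± 2.1 FPKM) and CD44 (44.0 ± 2.2 and 47.8 ± 1.7 FPKM) had adjusted p between 0.11 and 0.30. An FPKM depends on the isoform lengths it was computed with, so a switch of isoform can move the value of such genes.

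Of 45 splicing regulators, 8 rose and 1 fell, or 8 and 2 when adjusted over the list alone. The one that fell was PTBP3, a polypyrimidine tract binding protein listed under its older name ROD1, from 38.3 ± 0.79 to 28.1 ± 0.94 FPKM. RBMS1 went from 35.1 ± 0.55 to 42.0 ± 0.17 FPKM, HNRNPA1 from 265 ± 4.1 to 302 ± 8.1 FPKM and SFPQ from 164 ± 2.3 to 183 ± 2.6 FPKM. RBFOX2, which regulates splicing in mesenchymal cells, went from 44.5 ± 1.6 to 50.1 ± 0.62 FPKM (adjusted p = 0.015), a call lost without knockdown replicate 1 or 2 (adjusted p up to 0.052). RBM47 (39.6 ± 1.7 and 42.8 ± 0.84 FPKM in knockdown and control, adjusted p = 0.086), QKI (17.1 ± 1.4 and 17.9 ± 1.0 FPKM, adjusted p = 0.53) and PTBP1 (79.2 ± 2.1 and 76.7 ± 0.68 FPKM, adjusted p = 0.31) did not pass. The camera adjusted p of 0.030 became 0.072 without knockdown replicate 3 or control replicate 3, 0.053 after TPM scaling and 0.069 after the GC and length correction. With an estimated correlation the adjusted p was 0.31.

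Interferon, inflammatory and antigen presentation genes formed 3 of the lists. Of 36 interferon response genes, 17 fell and none rose, or 22 when adjusted over the list alone. HERC5 went from 45.1 ± 0.76 to 31.7 ± 0.72 FPKM, CMPK2 from 11.6 ± 0.23 to 7.24 ± 0.13 FPKM, IFI27 from 727 ± 38 to 502 ± 8.2 FPKM and RSAD2, the antiviral protein viperin, from 30.1 ± 1.0 to 20.8 ± 0.81 FPKM. By camera the adjusted p was 2.4e-08, and the adjusted p was 0.17 with an estimated correlation. Of 24 genes of NF-kB and inflammatory cytokines, 10 fell and none rose, or 11 when adjusted over the list alone. CXCL8, listed as IL8, went from 40.9 ± 0.51 to 27.7 ± 1.4 FPKM, TNFAIP2 from 395 ± 3.5 to 312 ± 10 FPKM and LCN2, lipocalin 2, from 49.7 ± 3.7 to 32.7 ± 3.8 FPKM, and RELB, an NF-kB subunit, had a log2 fold change of -0.25. Camera gave the list an adjusted p of 2.2e-05 (adjusted p = 0.17 with an estimated correlation). In antigen presentation 9 of 14 tested genes fell, or 9 with 1 rise when adjusted over the list alone (camera adjusted p = 5.2e-04; adjusted p = 0.17 with an estimated correlation). PDIA3, a chaperone of the peptide loading complex, went from 560 ± 6.3 to 476 ± 20 FPKM, and B2M, the light chain of MHC class I, had a log2 fold change of -0.22. HLA-C and HLA-B (-0.32 and -0.36) were measured on alternate haplotype contigs of the MHC, where near-identical copies share reads, so their values are uncertain. Without the 5 members on such contigs the list did not pass (adjusted p = 0.066).

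The output genes of the ERK pathway, of which 23 were tested, fell in 8 and rose in none, or 11 when adjusted over the list alone. The ERK phosphatases DUSP5 and DUSP6 went from 14.2 ± 0.59 to 9.31 ± 0.29 FPKM and from 65.5 ± 0.76 to 50.3 ± 2.7 FPKM, the EGF receptor ligand gene TGFA from 30.0 ± 0.47 to 22.7 ± 0.47 FPKM, and the receptor gene EPHA2 had a log2 fold change of -0.26. For the list as a whole, camera gave an adjusted p of 5.4e-05, and the adjusted p was 0.13 with an estimated correlation. The cholesterol synthesis genes fell in 15 of 23, or 17 when adjusted over the list alone, and SC5D, listed as SC5DL, rose (log2 fold change 0.13) in both counts, a call lost in each of the 6 fits that left out a library (adjusted p up to 0.12). FDFT1 went from 81.1 ± 3.6 to 62.4 ± 1.7 FPKM, and MVK, mevalonate kinase, had a log2 fold change of -0.37. Camera gave the list an adjusted p of 6.3e-08 (adjusted p = 0.076 with an estimated correlation).

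Hypoxia and glycolysis genes rose in 15 of 24 and fell in none, or 17 when adjusted over the list alone. BNIP3, a mitochondrial protein induced by hypoxia, went from 35.8 ± 0.72 to 55.3 ± 0.88 FPKM, PFKFB4 from 13.9 ± 0.42 to 18.3 ± 0.82 FPKM and NDRG1 from 36.6 ± 1.2 to 46.2 ± 2.0 FPKM, and the glycolytic enzyme gene PGK1 had a log2 fold change of 0.36. For the list as a whole, camera gave an adjusted p of 1.8e-07, and the adjusted p was 0.17 with an estimated correlation. S phase genes rose in 7 of 34 and fell in none, or 15 when adjusted over the list alone (camera adjusted p = 5.3e-06; adjusted p = 0.23 with an estimated correlation). TYMS, thymidylate synthase, went from 50.7 ± 0.87 to 108 ± 2.9 FPKM, while CCNE2, CHAF1A and FEN1 had log2 fold changes of 0.25, 0.20 and 0.12, and each of these 3 calls was lost in 4 of 6 fits that left out a library (knockdown replicate 1 or 2 or control replicate 3 for all 3, control replicate 2 for CCNE2 and CHAF1A and control replicate 1 for FEN1, with adjusted p up to 0.071). For mitosis genes 5 of 34 rose and 1, AURKB, fell, or 6 and 1 when adjusted over the list alone. KIF20A, CDK1, CENPF and FOXM1 had log2 fold changes of 0.20, 0.15, 0.22 and 0.18, of which the calls of CDK1, CENPF and FOXM1 were lost in 3, 2 and 5 such fits, all of them without knockdown replicate 2 and without control replicate 3 among others, and that of AURKB (-0.14) in 5 (adjusted p up to 0.12 over the 4 genes). The mitosis list had a camera adjusted p of 0.030, which rose to between 0.052 and 0.16 in the 4 fits without knockdown replicate 1 or 2 or control replicate 2 or 3, to 0.069 after the GC and length correction and to 0.18 with fry, and the adjusted p was 0.55 with an estimated correlation. Ribosomal protein genes rose in 9 of 30 and fell in none, or 11 when adjusted over the list alone, by small amounts such as 0.16 for RPLP0, 0.15 for RPS9, 0.14 for RPL13A and 0.12 for RPL3 on the log2 scale, each lost in 4 or 5 of 6 fits that left out a library, among them those without knockdown replicate 1 or 2 and control replicate 1 or 2 (adjusted p up to 0.10). The camera adjusted p was 6.4e-05, and the adjusted p was 0.43 with an estimated correlation and 0.068 with fry. Processed pseudogenes share reads with ribosomal protein genes, so these values are uncertain.

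The lists described next were not called by camera, and the adjusted p given for each is that of camera over the 29 lists. With fry, 4 of them passed: integrins and basement membrane (adjusted p = 0.0040), lung lineage (0.029), growth factor receptors (0.044) and the stress responses (0.044). Of 20 YAP and TAZ targets, 5 rose and 1 fell (adjusted p = 0.085), with the same counts when adjusted over the list alone. The matricellular gene CCN2, listed as CTGF, went from 3.91 ± 0.12 to 5.56 ± 0.26 FPKM, with PTPN14, IGFBP3 and F3 at 0.32, 0.25 and -0.34 on the log2 scale, the F3 call being lost without knockdown replicate 2 or control replicate 1 or 3 (adjusted p up to 0.056). The list passed at an adjusted p of 0.044 without knockdown replicate 3 and of 0.032 without the filter on low genes. Integrins and basement membrane genes went both ways, with 3 higher and 6 lower of 20, or 5 and 8 when adjusted over the list alone (adjusted p = 0.26). ITGB4 of the hemidesmosome went from 70.3 ± 0.86 to 51.4 ± 1.2 FPKM, the laminin gene LAMA3 from 61.4 ± 0.65 to 72.3 ± 4.0 FPKM, and ITGB5 had a log2 fold change of -0.47. Of 18 growth factor receptors, 1, ROR1 (log2 fold change 0.27), rose and 5 fell, among them ERBB3 and ERBB2 (-0.27 and -0.15, the latter lost without control replicate 2 at an adjusted p of 0.057), also when adjusted over the list alone (adjusted p = 0.24). Of 25 genes of the unfolded protein and amino acid stress responses, 5 rose and 12 fell, or 7 and 13 when adjusted over the list alone (adjusted p = 0.085), with ATF3, SLC7A5 and XBP1 at -0.40, -0.24 and -0.18 and DDIT4 at 0.38 on the log2 scale. That list passed at an adjusted p of 0.027 without the filter. Only 6 lung lineage genes were tested, and 2 fell, or 3 when adjusted over the list alone (adjusted p = 0.085), MUC5B from 11.5 ± 0.56 to 8.12 ± 0.79 FPKM and LPCAT1 from 79.3 ± 1.3 to 72.3 ± 0.68 FPKM. The list passed at an adjusted p of 0.042 without control replicate 1 and of 0.019 without the filter.

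Of 15 NRF2 and xenobiotic metabolism genes 1 rose and 2 fell, or 3 and 6 when adjusted over the list alone (adjusted p = 0.31). CYP1B1 had a log2 fold change of 0.29, and HMOX1 and ABCC3 had -0.29 and -0.23. HMOX1 kept its call only without knockdown replicate 3 and ABCC3 only without control replicate 1 among the 6 fits that left out a library (adjusted p up to 0.14). Of 13 genes of the RNA interference machinery 1, DROSHA, rose, a call lost in every fit that left out a library except that without knockdown replicate 3 (adjusted p up to 0.14), and none did when adjusted over the list alone (adjusted p = 0.26). Of 28 mitochondrial electron transport genes 2 fell and none did when adjusted over the list alone (adjusted p = 0.95). They were CYC1, whose call was lost in each of those 6 fits, and NDUFB10, which kept its call only without knockdown replicate 3 or control replicate 2 (adjusted p up to 0.12). The median of this list was 0.01 and its mean -0.01. Of 10 replication-dependent histone genes 3 fell, also when adjusted over the list alone (adjusted p = 0.66). Of these HIST1H1C (-0.21) was called in each of those fits. HIST2H2BE kept its call only without control replicate 3, and HIST1H2BC only without knockdown replicate 3 or control replicate 1 (adjusted p up to 0.12). Of 15 common reference genes 4 rose (PGK1, HPRT1, GAPDH and RPLP0) and 1, YWHAZ, fell, or 6 and 1 when adjusted over the list alone (adjusted p = 0.16). The calls of GAPDH (0.15), RPLP0 and YWHAZ (-0.14) were each lost in 5 of 6 fits that left out a library, all except that without knockdown replicate 3 for GAPDH and RPLP0 and without knockdown replicate 2 for YWHAZ (adjusted p up to 0.10).

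The gene with the largest called rise apart from multi-copy or pseudogene rows was CD99L2 on chromosome X (149934810 to 150067289), a membrane protein related to CD99, from 7.37 ± 0.58 to 18.2 ± 0.42 FPKM (log2 fold change 1.20, limma adjusted p = 8.7e-05). TYMS (chromosome 18, 657604 to 673578) followed at 1.07, and its neighbour ENOSF1, which overlaps its end, stood at 15.8 ± 0.59 and 15.8 ± 0.76 FPKM in knockdown and control. The ID3, ID2 and THBS1 rises belong to the same set. RAPGEF6 rose with a log2 fold change of 0.82, but its knockdown libraries held 5.29, 9.87 and 11.2 FPKM, and the call was lost in every fit that left out a library except that without knockdown replicate 1 (adjusted p up to 0.13). RARRES1 (0.77) and the non-coding or pseudogene rows RP11-613M10.6 (0.93), RP11-490K7.4 (1.17) and Z83840.1 (0.79) were lost in 4 or 5 of those fits, all of them without knockdown replicate 1, knockdown replicate 3 or control replicate 1 (adjusted p up to 0.12). A copy of the small nuclear RNA U1 on chromosome 17 had a log2 fold change of 1.46 and the pseudogene row AC108463.2 one of 1.26, and near-identical copies make both values uncertain. Control replicate 3 was listed at 0 for AC108463.2 and RP11-490K7.4, so their rises rest in part on a 0, and the fall of AC067852.1 rests in part on a value in knockdown replicate 3 that is 0 in effect. Apart from ESRP1, the largest falls were those of GDF15, a secreted stress-responsive factor, from 24.7 ± 1.8 to 10.7 ± 0.30 FPKM (-1.13), and S100A14, an epithelial calcium-binding protein, from 25.1 ± 1.5 to 11.5 ± 0.90 FPKM (-1.06). SPTSSB, a subunit of serine palmitoyltransferase, went from 20.7 ± 0.51 to 10.7 ± 0.26 FPKM, TMEM87A from 40.7 ± 0.96 to 22.5 ± 1.3 FPKM, PADI2 from 6.10 ± 0.16 to 2.85 ± 0.30 FPKM and A4GALT from 3.47 ± 0.14 to 1.51 ± 0.16 FPKM. CPHL1P and AC108463.1 had log2 fold changes of -0.94 and -0.99, and KRT6A one of -0.87. PTGDS (-0.97), MIR205HG, listed as CTA-55I10.1 (-0.94), and AC067852.1 (-1.02) were called in the full data but lost in 3, 3 and 5 of the 6 fits, all of them without knockdown replicate 2 (adjusted p up to 0.14).

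Most markers of other cell types were low. Of 10 leukocyte markers, 2 were listed at 0 in all libraries, which can be a failed estimate, and 7 of the other 8 averaged below 1 FPKM. The remaining marker, CD68, which many cells express, was not called, at 12.9 ± 0.73 and 14.8 ± 0.80 FPKM in knockdown and control. Of 7 endothelial markers 6 were matched, 1 was listed at 0, and 4 of the other 5 averaged below 1 FPKM, with KDR at 1.36 FPKM. Of 10 fibroblast markers 8 averaged below 1 FPKM. COL1A1, at 9.17 FPKM, was not called (limma adjusted p = 0.57), and LUM, at 27.6 FPKM, was the one that rose.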

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

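The GC and length correction, the removal of haplotype and unplaced contigs and the constant shift of the knockdown libraries were chosen after the data were seen. ESRP1 and ESRP2 kept their direction and their calls under every alternative. The replicate numbers do not pair the libraries (correlations of same-number deviations between -0.017 and 0.070, and 2 of 6 libraries correlated best with their own number). With the replicate block 1433 genes were called, 491 of them higher and 942 lower, and of the 2278 genes called without it 1371 were shared. Without a filter 26835 rows were tested and 1413 called, 497 higher and 916 lower, with the adjustment spread over more rows, and 21 lists were called, the gains being YAP and TAZ targets, the stress responses and lung lineage. A pseudocount of 0.1 raised the genes changed at least 2-fold from 9 to 22, since low genes then count more, and TPM scaling raised them to 14. That scaling divided the libraries by 0.585 to 0.602 before the pseudocount of 1 was added, so low genes also counted more. How much of the rise to 14 this explains was not tested. Leaving out a library gave 1187 to 1983 genes changed, 403 to 850 higher and 761 to 1133 lower, with fewer samples in the fit. No called list passed with an estimated correlation (0 lists, from 18). Of 141 called genes followed through the alternatives, those of the naming rule and those looked up afterwards, 97 were called in every fit that left out a library, and none changed direction. The groups of all 2278 called genes did not overlap, so leaving out a library could not have changed a direction. Of the lists, 16 of 18 called ones were called in every such fit, all but splicing regulators and mitosis. Among the genes and lists followed, changes of sign occurred for 2 lists and a gene that were not called, close to 0. The electron transport list had a mean of 0.0058 after the GC and length correction, 0.0065 after the constant shift and from -0.018 to 0.014 without a library. The RNA interference list, with a mean of 0.015, had means from -0.010 to 0.036 without a library. ENOSF1 stood at -0.0083 after TPM scaling and from -0.023 to 0.041 without a library; the cause was not tested. Depth differed between libraries and is known only as an estimate, which limits what the low genes show.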

Other observations

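Tests in this part that were chosen after the result was seen are the GC and length correction and the constant shift as alternatives and those of ENOSF1, of the other S phase genes, of PTPRC, of list members outside the MHC region, and of the number of calls after GC and length correction, together with the gene families and the genes looked up here. Grouping tested genes by the root of their symbol gave 174 families of at least 8 members, of which 8 passed camera after adjustment and none passed with an estimated correlation (adjusted p = 0.96). Clustered protocadherins, cell surface cadherins best known from neurons, were among the higher families: 7 of 10 tested beta-cluster genes (PCDHB) rose and none fell, with a median log2 fold change of 0.23 (adjusted p = 2.2e-05), and 3 of 8 alpha-cluster genes (PCDHA) rose. Members of these clusters resemble each other or share exons, so their values are uncertain. Of 13 keratin (KRT) genes 10 fell, and of 10 interferon regulatory factor (IRF) genes 5 fell. Each of these 4 families kept the sign of its median after median-ratio scaling, TPM scaling and the GC and length correction.

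Some genes were looked up after the lists were seen. BMP4, a ligand of the BMP pathway, rose from 27.6 ± 0.38 to 41.7 ± 2.8 FPKM and ID4 from 7.61 ± 0.39 to 11.9 ± 1.0 FPKM. A candidate explanation for the joint rise of ID1, ID2, ID3 and BMP4 is a higher BMP response. It was tested on 13 other genes listed as BMP-responsive. Among them are components of the pathway itself (SMAD1, SMAD5, RGMB and TWSG1), so the set is a mixed readout of the response. Camera did not call the 13 genes (adjusted p = 0.95 over these and the 29 lists). Their median was 0.021 on the log2 scale: ATOH8 rose and HES1 and JAG1 fell. The bound set in advance, a median at or below 0.05, was met and would have counted against the hypothesis. After the result was seen it was judged the wrong bound, because members went both ways and the median lies within their spread of it, so the hypothesis stays open. The value taken to decide was also changed after the result, from the camera p to the median that the bound names.

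The first pattern weighed is that of many small changes with more genes lower. The excess of lower genes depends on centring. After median-ratio scaling, whose factors were close to 1, 57.5% of calls were lower, and after TPM scaling 67.0%. Scaling therefore stays open, although the bound set in advance counted against it. Of 543 genes called from replicates 2 and 3 alone, 95.4% had the same sign between the replicate 1 libraries, whose depths are nearly equal. The share was 70.2% of all tested genes, which argues against depth as the source of the changes. No chromosome had a median log2 fold change farther from 0 than 0.028, which argues against gain or loss of whole chromosomes. Such medians cannot show copy changes of smaller segments, which stay open. Removal of trends on GC content and length left 51.1% of calls lower, which by the bound set in advance counted for these trends as the cause. A constant shift of 0.013 alone left 53.1%, so these trends and centring cannot be told apart for the excess, which may be technical. This reading, like that of scaling, was adopted after the results were seen. With the trends removed 2517 genes were called, of which 1998 were among the 2278 called without the correction. These counts argue against the trends as the source of the number of changes. Only 1 of the 10 splits of the 6 libraries, the real one, gave as many calls (2278, with 4 the highest of the others), and 10 splits are too few for a share under 0.05.

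The second is the rise of TYMS. Reads from the overlapping gene ENOSF1 are argued against as the source, since the log2 fold change of ENOSF1 was 0.0034. More cells in S phase do not account for it either, as the other 33 S phase genes had a median of 0.091 (SD 0.081, from -0.061 to 0.25), far below 1.07. An effect of the constructs other than through the ESRP proteins stays open, because each group carries its own.

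The third is the lower interferon, antigen presentation and inflammatory genes. Leukocytes in the control cultures are argued against by PTPRC, at 0.229 FPKM in the controls, with 7 of the 8 leukocyte markers listed above 0 below 1 FPKM; CD68, the most abundant, was not called (12.9 ± 0.73 and 14.8 ± 0.80 FPKM in knockdown and control). Reads shared between MHC haplotype copies cannot be the whole source for the pooled lists, because 60 of 67 members outside the MHC region had negative fold changes, with a median of -0.15. Most of these members belong to the interferon (36 tested) and inflammatory (24 tested) lists, so the pooled count does not decide for antigen presentation. Without its 5 members on haplotype contigs that list did not pass by camera, so shared reads stay open as a source of its rank. Whether the innate genes follow the ESRP proteins or differ because the constructs of the groups differ stays open, since no second construct was analysed here.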
